A study of Mus musculus and Homo sapiens with 12 samples.

How the data were processed

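RNA was measured by sequencing in 12 libraries: 4 of the human T-ALL line KOPTK1 (DMSO or a gamma-secretase inhibitor for 72 h) and 8 of sorted mouse T-ALL cells from mice on 4 diets, 2 libraries per group. Per the labels' protocols, RNA was purified with RNeasy columns and libraries were made with a strand-specific kit. The submitters' processing notes name STAR, edgeR and the builds hg19 and mm10, without versions or roles. The gene model, gene length and counting tool are not given in the sources used here. The values deposited by the authors were FPKM per gene and library, 1 table per species, with 11513 human and 10430 mouse genes. All sample columns were used. The tables were analysed separately because they were normalised separately.

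Once each library's divisor was fixed, the FPKM values of every listed gene stood in whole-number ratios within a relative 1e-09, and read numbers were taken as the smallest whole numbers in these ratios. The gene length that follows was whole within 0.01 bp for 95.8% of human and 99.9% of mouse genes. The reads of 484 human and 13 mouse genes were multiplied to make it whole, and 5 human genes stayed open, so the reads are estimates. The divisor was 0.939 of the listed reads in DMSO replicate 1, and 1.01 to 1.07 of them in the other libraries. In simulated values the reads came back exactly for 96.6% of genes with 4 columns and 99.9% of genes with 8 columns. Recovered reads over the listed genes were 22933342 and 25295686 (DMSO) and 28557903 and 42232859 (inhibitor) in KOPTK1. In mouse TALL2 and TALL3 they were 21253323 and 16085830 at 8 g/kg, 16009143 and 25840513 at 0.8 g/kg, 37687253 and 16811390 at 0.4 g/kg, and 18619420 and 14222895 at 0 g/kg. The median recovered length was 3180 bp in mouse, near that of transcripts, and 29960 bp in human, so human FPKM are low for their depth and are compared only within the human table. Within that table the FPKM filters and the pseudocount weigh more on genes with a long recovered length. Rankings and list medians there depend on it. A chi-square test of the recovered reads found replicate libraries to differ beyond counting noise in every group, with chi-square over degrees of freedom of 5.73 to 93.1.

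Symbols were taken from the tables, and the 318 mouse genes without one were named from a reference list that held 10427 of the mouse identifiers. Mouse coordinates are from the GRCm38 annotation, the assembly that mm10 names. Human coordinates were not analysed here. Genes with a mean of at least 1 FPKM over the libraries of a table were tested, 6679 in human and 9943 in mouse. The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The mouse diets were fitted together, so that all share 1 estimate of the spread. The slope used the diets ranked by falling valine (0, 1, 2 and 3), and an F test compared the 3 restricted diets.

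Before the data were examined, 44 gene lists of pathways and cell types were written, and those with at least 5 tested members (33 in human, 36 in mouse) were tested with limma's camera at a preset correlation of 0.01. The genes named in the text follow a rule also written then. It takes up to 5 rises and 5 falls past the threshold with at least 5 FPKM in the higher group, filled to 3 per direction by the smallest p where fewer passed. It adds fixed genes of the NOTCH, valine and complex I questions. From each list past its threshold it adds up to 4 members by size of change or, where no member passed, 2 by smallest p. Of the fixed genes NRARP, PTCRA, IL7R and NDUFA10 in human and Chac1 and Slc7a11 in mouse were not among the tested genes. Where genes are said to pass adjusted over a list alone, the Benjamini-Hochberg adjustment used only the genes of that list. Such counts are not adjusted over the other lists or genes and are not calls.

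The alternatives planned were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 5 FPKM, median-of-ratios and quantile scaling, no variance trend, the replicate number as a block, only the diets compared, camera with an estimated correlation, fry, and leaving out each library. Chosen after seeing the data were limma-voom on the recovered reads, the diet fits without both 0.4 g/kg libraries, the lists without the ATF4 targets they share, and the list tests between restricted diets. After the main results had been computed, the tests were also run on simulated data, with 67, 67 and 66 genes changed by 1.5, 2 and 4 fold, and the simulated spread was corrected once after that. Noise was drawn independently for each gene and library, with no difference shared between libraries named alike. In these data 11.9% of genes changed by 1.5-fold and 80.3% of those changed by 4-fold were recovered for 0 against 8 g/kg. A planted list of 30 genes raised by 1.5-fold had an adjusted p with an estimated correlation of 0.0524 in KOPTK1 and 0.00731 for 0 against 8 g/kg. At camera's preset correlation these were 8.5e-106 and 6.4e-29. In KOPTK1 the estimated correlation thus missed a list that did change, so a list that did not pass with it may still have changed. The result of 1 gene is not reported here.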

Results

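The 12 libraries came from 2 systems of T-cell acute lymphoblastic leukaemia (T-ALL). The first was KOPTK1, an established human T-ALL cell line, grown for 72 h with the carrier DMSO or with a gamma-secretase inhibitor (gSI, Compound E), with 2 libraries per condition. Gamma-secretase is the protease that frees the active part of NOTCH1 from the cell membrane. The second was mouse T-ALL driven by an activated NOTCH1 (the delta-E form), transplanted into C57BL/6 mice and kept for 3 weeks on diets that differed in the essential amino acid valine. GFP-positive leukaemic cells were sorted from the spleen. The 4 diets held 8 g/kg of valine (the control), 0.8 g/kg, 0.4 g/kg and 0 g/kg, with 1 library named TALL2 and 1 named TALL3 per diet. The labels do not say what these names mark. The treatment protocol also speaks of 0.8 or 0.4 g/L valine in drinking water beside a valine-deficient diet, so the doses are used here only as ranked diets named by the g/kg figure.

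Values were FPKM, for 11513 human and 10430 mouse genes. Read numbers recovered from the steps between FPKM values ran from 22933342 to 42232859 per KOPTK1 library and from 14222895 to 37687253 per mouse library. Fold changes are on the scale of log2(FPKM + 1), which understates the change of genes with low FPKM. Errors of mean FPKM are SDs over n = 2 libraries per group. The labels do not state that libraries of one group came from separate cultures or animals. P-values therefore measure only the spread between these libraries, which may be technical. In mouse that spread holds a difference between TALL2 and TALL3 that recurred between diets, so it is not only random noise. Deviations from the diet means correlated at 0.363 to 0.743 across genes between the diets other than 0.4 g/kg. The main fit leaves this difference in the spread.

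The first comparison asked which mRNAs changed when gamma-secretase, and with it NOTCH1 cleavage, was blocked in KOPTK1 cells. NOTCH target genes fell steeply: HES1, a transcriptional repressor switched on by NOTCH, was at 6.45 ± 0.376 FPKM with DMSO and at 0.0342 ± 0.0126 FPKM with gSI, and HES4 of the same family was at 25.4 ± 2.13 and 0.0639 ± 0.0140 FPKM. MYC, the growth regulator that NOTCH1 induces in T-ALL, fell from 16.6 ± 0.799 to 4.75 ± 0.00221 FPKM. Genes of DNA replication, cytosolic ribosomes, nucleotide synthesis, glycolysis and tRNA charging fell as groups, and genes of the unfolded protein response and of lysosomes rose. Fry, which tests each list alone, called a number of lists within 1.5 times of camera's 13. In camera these list results rest on the preset correlation. With an estimated correlation the adjusted p of the 13 lists that passed lay between 0.419 and 0.948. A simulated list raised by 1.5-fold did not pass with an estimated correlation either (adjusted p = 0.0524). In KOPTK1 that setting therefore cannot decide between a change and none. In limma, 3547 of 6679 tested genes passed an adjusted p of 0.05, of which 1524 rose and 2023 fell, and 15 rose and 76 fell by at least 2-fold on the log2(FPKM + 1) scale.

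All 14 tested members of the NOTCH target list fell, with a median log2 fold change of -1.74 (limma's camera, adjusted p = 5.4e-15; adjusted p = 0.419 with an estimated correlation). Among them DTX1, a ubiquitin ligase of the NOTCH pathway, changed by -2.52 (SE 0.0754, adjusted p = 6.7e-21) and GIMAP5 by -2.37 (SE 0.0769, adjusted p = 4.1e-20). NOTCH3 changed by -2.36 (SE 0.0727, adjusted p = 1.5e-20) and NOTCH1 itself by -0.36 (SE 0.0772, adjusted p = 3.5e-04). Besides HES4 (-4.63, SE 0.0775), the largest falls on the log2(FPKM + 1) scale among genes with at least 5 FPKM in the higher group were those of CD1E (-3.62, SE 0.0830) and CD1B (-3.18, SE 0.0814), both made by cortical thymocytes, of the ERK phosphatase DUSP6 (-3.21, SE 0.0790) and of GIMAP7 (-2.93, SE 0.0836). All 11 tested thymocyte and T-ALL markers fell (median -0.47, adjusted p = 1.7e-05; adjusted p = 0.894 with an estimated correlation). Among them CD3D went from 122 ± 0.969 to 48.8 ± 5.41 FPKM, and the T-lineage factors TCF7 (-0.80), LEF1 (-0.65) and BCL11B (-0.59) fell too.

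Growth-related lists fell together. Of 34 tested DNA replication genes, 29 fell and 5 did not pass the test (median log2 fold change -0.49, camera adjusted p = 8.5e-10). The largest falls were those of the helicase subunits MCM6 (-0.94) and MCM7 (-0.83), the licensing factor CDT1 (-0.89) and the ribonucleotide reductase subunit RRM2 (-0.84). Of 72 cytosolic ribosomal protein genes, 56 fell and RPS26 alone rose (median -0.40, adjusted p = 1.1e-09), with RPL12 at -0.87 and RPL3 at -0.80. In serine, one-carbon and nucleotide synthesis 21 of 25 genes fell and CAD rose (median -0.43, adjusted p = 1.1e-06), including IMPDH2 (-0.78) and MTHFD1 (-0.71). In glycolysis 13 of 17 fell and the lactate carrier SLC16A1 rose (median -0.46, adjusted p = 3.5e-05), including LDHA, from 44.0 ± 0.0116 to 20.1 ± 0.270 FPKM, and ENO1 (-0.93). Among 49 MYC targets 29 fell and 4, NOP56, ODC1, CAD and TFRC, rose (median -0.24, adjusted p = 9.0e-05). In mitosis 24 of 36 fell (median -0.23, adjusted p = 0.00192), with DLGAP5 at -0.71 and AURKB at -0.56. With an estimated correlation the adjusted p of these 6 lists lay between 0.894 and 0.948. Without gSI replicate 2 the mitosis list did not pass (median -0.21, adjusted p = 0.0720), nor did it with a filter at a mean of 5 FPKM (adjusted p = 0.131).

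Genes of tRNA charging, which load amino acids onto tRNAs, also fell with gSI. VARS, the cytosolic valyl-tRNA synthetase, went from 2.06 ± 0.0139 to 1.17 ± 0.0543 FPKM (log2 fold change -0.50, SE 0.0622, adjusted p = 1.9e-07), while VARS2, its mitochondrial counterpart, rose by 0.17 (SE 0.0673, adjusted p = 0.0392). Of 21 tested cytosolic aminoacyl-tRNA synthetase genes, 15 fell and WARS rose (median -0.38, adjusted p = 0.00151; adjusted p = 0.894 with an estimated correlation), among them YARS (-0.66), DARS (-0.56), GARS (-0.56) and LARS (-0.52). Nuclear genes of complex I, the first enzyme of the mitochondrial respiratory chain, did not pass as a list (median -0.04, adjusted p = 0.839). Values were listed for 37 subunits, of which 23 were tested. NDUFB4, NDUFB5, NDUFB10 and NDUFS5 fell and the other 19 did not pass; these 4 were chosen for naming after their values were seen. NDUFS1, its largest subunit, was at 3.91 ± 0.278 FPKM with DMSO and at 3.43 ± 0.0358 FPKM with gSI (adjusted p = 0.103). Among 51 mitochondrial ribosomal protein genes 22 fell, including MRPS15 (-0.73), and MRPL53, MRPL55 and MRPS12 rose (median -0.12, adjusted p = 0.0401; adjusted p = 0.936 with an estimated correlation). The call of this last list ended with voom on the recovered reads (adjusted p = 0.127), with a filter at a mean of 5 FPKM (0.501), and without DMSO replicate 2 (median -0.15), gSI replicate 1 (-0.12) or gSI replicate 2 (-0.17).

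Of 24 genes of the unfolded protein response 20 rose and 4 did not pass (median 0.37, adjusted p = 7.9e-08; adjusted p = 0.894 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, went from 17.6 ± 0.0508 to 34.8 ± 1.24 FPKM, beside SYVN1 (0.77) and HYOU1 (0.74). Of 27 lysosome and autophagy genes of the TFEB network 19 rose (median 0.23, adjusted p = 1.2e-06; adjusted p = 0.894 with an estimated correlation), including the lysosomal enzymes NEU1 (1.16, SE 0.0778) and CTSA (0.95) and the autophagy genes GABARAPL1 (0.76) and MAP1LC3B (0.71). The largest rises on the log2(FPKM + 1) scale among genes with at least 5 FPKM in the higher group were those of DHRS2 (2.04, SE 0.0821), AMH (1.37, SE 0.0856), NEU1, ATF5 (1.16, SE 0.0945), a stress-responsive transcription factor, and MFAP4 (1.15, SE 0.0851). In the heat-shock and dissociation list 8 of 15 genes rose, with JUND at 0.91, and HSP90AB1 and HSPB1 fell (median 0.17, adjusted p = 0.0456; adjusted p = 0.948 with an estimated correlation), and voom ended that call (adjusted p = 0.0623), as did a filter at a mean of 5 FPKM (0.0903) and no filter (0.0644). It also ended without DMSO replicate 2 (median 0.13), gSI replicate 1 (0.16) or gSI replicate 2 (0.15), and the median was 0.26 without DMSO replicate 1 (adjusted p = 0.0243).

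**Figure D1:**
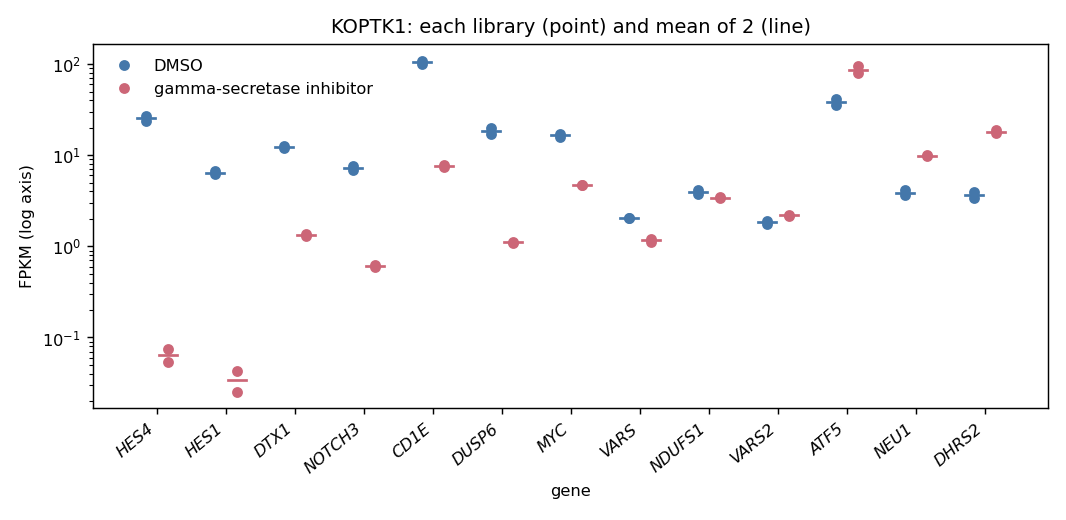
FPKM (log axis) of 13 genes in each KOPTK1 library, as points, with the mean of the 2 libraries per condition as a line. HES1 was at 6.45 FPKM with DMSO and 0.0342 FPKM with the inhibitor, VARS at 2.06 and 1.17, and DHRS2 at 3.67 and 18.1.

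Of the 33 lists tested in KOPTK1, 13 passed. Adjusted over the list alone, the counts of these lists were the same except for cytosolic ribosomal proteins (58 fell), mitochondrial ribosomal proteins (20 fell) and lysosomal genes (20 rose). The ATF4 target list, genes induced by amino acid shortage, held 12 genes that rose and 14 that fell and did not pass (median -0.08, mean 0.03, camera direction up, adjusted p = 0.697). Genes named here as exceptions to a list's direction were chosen after their values were seen. In simulated data 97.0% of genes changed by 1.5-fold were recovered in this comparison, and 15 of 213 calls were false. The balance of rises and falls depended on scaling: median-of-ratios scaling gave 1787 rises and 2078 falls, and quantile scaling turned it to 1981 rises and 1852 falls. Without gSI replicate 2, the deepest KOPTK1 library, the number of called genes was 2207. Medians moved by over 1.5 times with a pseudocount of 5, which shrinks the changes of low genes: to -0.82 for NOTCH targets, -0.28 for DNA replication, -0.26 for glycolysis, -0.20 for synthetases and for serine synthesis, -0.14 for mitosis, -0.13 for MYC targets, -0.07 for mitochondrial ribosomal proteins, 0.23 for the unfolded protein response, 0.11 for lysosomal genes and 0.08 for heat shock. Other such moves were NOTCH targets with no filter (-0.94), both MYC targets (-0.37) and lysosomal genes (0.39) with a filter at a mean of 5 FPKM and cytosolic ribosomal proteins with quantile scaling (-0.24).

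The diets without valine and with 8 g/kg valine were compared to see which mRNAs of leukaemic cells moved when dietary valine was absent. Genes induced by the transcription factor ATF4 when amino acids run short were higher without valine. Asparagine synthetase, Asns (ENSMUSG00000029752, chromosome 6, 7675169 to 7693254, minus strand), was at 2.02 and 2.90 FPKM in the control libraries and at 69.2 and 84.6 FPKM in the 0 g/kg libraries. Nuclear genes of complex I were slightly lower, DNA replication genes were higher, neutrophil markers were far higher and erythroid markers were far lower. With an estimated correlation the adjusted p of the 21 lists that passed lay between 0.390 and 0.681. No single gene passed the threshold: limma called 0 of 9943 tested genes, with 1025 at an unadjusted p under 0.05 where chance gives 497, and voom on the recovered reads called 0, with 933. The smallest adjusted p was 0.121, so gene values below are measurements that did not pass, and calls refer to lists.

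Of 36 tested lists, 21 passed. The ATF4 targets rose with a median log2 fold change of 0.84 (34 genes, camera adjusted p = 9.5e-20; adjusted p = 0.390 with an estimated correlation). In 30 of them both 0 g/kg libraries lay above both controls, where chance gives 5.67 and the share over all genes 6.50, and 17 passed when adjusted over the list alone. Besides Asns, Ppp1r15a, which restores translation after stress, was at 10.9 ± 5.05 FPKM in the control and 49.3 ± 5.06 without valine, and Ddit3 (CHOP) at 9.64 ± 0.635 and 18.6 ± 6.86. Trib3 was at 0.339 ± 0.226 FPKM in the control, and without valine at 3.04 FPKM in TALL2 and 21.4 FPKM in TALL3. Sesn2 was at 2.55 ± 0.211 FPKM in the control, and without valine at 3.32 and 15.1 FPKM. In the same libraries neutrophil markers rose and erythroid markers fell. Bcat1, which transfers the amino group of branched-chain amino acids such as valine, was at 2.70 ± 0.752 and 8.21 ± 0.863 FPKM (log2 fold change 1.33, SE 0.221, adjusted p = 0.202), and Bcat2 at 24.7 ± 0.961 and 28.5 ± 3.34.

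Amino acid transporters rose (19 genes, median 0.16, adjusted p = 0.00439; adjusted p = 0.390 with an estimated correlation; Slc1a5 passed when adjusted over the list alone). Slc1a5 was at 87.7 ± 0.767 FPKM in the control and 119 ± 7.46 FPKM without valine, Slc3a2 at 63.7 ± 3.25 and 104 ± 20.5, and Slc7a5, which carries valine, at 91.6 ± 2.58 and 143 ± 7.91. Of the transporter list 7 genes were also ATF4 targets, and without them it did not pass (median -0.004, adjusted p = 0.852). Cytosolic aminoacyl-tRNA synthetases rose (23 genes, median 0.18, adjusted p = 0.00179; adjusted p = 0.613 with an estimated correlation), led by Sars (48.0 ± 0.568 and 83.5 ± 2.70 FPKM) and Aars (30.2 ± 0.643 and 57.1 ± 8.84), and passed without the 4 shared ATF4 targets (adjusted p = 0.0238). Its call ended without the TALL2 library at 0 g/kg (median 0.21, adjusted p = 0.0967). Vars was at 148 ± 2.55 and 160 ± 2.15 FPKM and Vars2 at 18.2 ± 1.92 and 19.1 ± 0.704. The transporter median was 0.29 without the TALL3 control and 0.10 with a pseudocount of 5, and the synthetase median was 0.11 without the shared ATF4 targets.

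Complex I subunit genes fell with a median of -0.18 over 36 genes (adjusted p = 1.6e-05; adjusted p = 0.613 with an estimated correlation, and 0.285 with fry). In 20 of them both 0 g/kg libraries lay below both controls, in Ndufb2 above, where chance gives 6.00 per direction and the share over all genes 8.25 lower and 6.88 higher. Adjusted over the list alone limma called 0 of them, with 6 lower at an unadjusted p under 0.05, and voom called 0 genes. Neutrophil markers rose in the same libraries. Ndufb3 was at 30.1 ± 0.937 and 21.6 ± 3.12 FPKM and Ndufs3 at 32.9 ± 1.79 and 25.5 ± 2.73, whereas Ndufs1 (50.6 ± 0.338 and 50.4 ± 1.57) differed by less than the spread between libraries and Ndufa10 was at 112 ± 7.91 and 97.4 ± 17.9. Leaving out each of the 8 libraries in turn gave medians from -0.23 to -0.13, all past the threshold. Subunits of complexes II to IV fell by a median of 0.15 (24 genes, adjusted p = 5.6e-04; adjusted p = 0.613 with an estimated correlation), with Uqcrfs1 at 125 ± 0.128 and 91.1 ± 3.94 FPKM, as did genes of the TCA cycle (median -0.13, adjusted p = 0.0272), mitochondrial ribosomal proteins (median -0.09, adjusted p = 0.00222) and mitochondrial stress and import (median -0.11, adjusted p = 0.0352). With an estimated correlation the adjusted p of these 3 lists was 0.613 to 0.681. Without the TALL3 library at 0 g/kg the adjusted p became 0.139 for complexes II to IV, 0.866 for the TCA cycle, 0.204 for mitochondrial ribosomal proteins and 0.169 for stress and import. The last list also ended without either 0.8 g/kg library, without the TALL3 control and without the TALL2 library at 0 g/kg (adjusted p 0.0605 to 0.142), with a filter at a mean of 5 FPKM (0.0883) and with only the 2 diets compared (0.0734), and the TCA cycle without the TALL3 control (0.136). With the trend over gene length removed the complex I median was -0.11. Medians without TALL3 at 0 g/kg were -0.03 for the TCA cycle, -0.05 for mitochondrial ribosomal proteins and -0.06 for stress and import. Without TALL2 at 0 g/kg they were -0.23 for complexes II to IV and -0.20 for the TCA cycle, and without the TALL3 control -0.05 for stress and import.

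Among lists of growth, DNA replication rose (41 genes, median 0.28, adjusted p = 1.2e-09; adjusted p = 0.613 with an estimated correlation; 29 genes higher in both libraries, chance 6.83, share over all genes 7.84), with Cdc6 at 14.2 ± 1.45 and 23.9 ± 3.64 FPKM. The mitosis list fell (34 genes, median -0.27, adjusted p = 2.0e-04; adjusted p = 0.681 with an estimated correlation; 11 lower in both libraries, chance 5.67, share over all genes 7.79), with Cenpa at 54.0 ± 1.34 and 28.6 ± 12.1, but did not pass without the TALL2 library at 0 g/kg (median -0.03, adjusted p = 0.560). RNA polymerase III genes fell (23 genes, median -0.14, adjusted p = 5.6e-04; adjusted p = 0.390 with an estimated correlation), as did tRNA processing (median -0.10, adjusted p = 0.00543) and ribosome biogenesis (median -0.09, adjusted p = 0.00142), both at an adjusted p of 0.613 with an estimated correlation. The tRNA processing list did not pass without the TALL3 library at 0 g/kg (adjusted p = 0.102), nor ribosome biogenesis without the TALL2 control (0.0855). Serine, one-carbon and nucleotide synthesis rose (median 0.07, adjusted p = 0.00837; adjusted p = 0.681 with an estimated correlation), with Psat1 at 93.6 ± 7.89 and 181 ± 2.27 FPKM. It did not pass without its 5 ATF4 targets (adjusted p = 0.281), without the TALL2 control (0.0872) or without the TALL2 library at 0 g/kg (0.560). Myc was at 245 ± 31.9 and 137 ± 35.0 FPKM (adjusted p = 0.358), Hes1 at 88.1 ± 16.6 and 142 ± 27.6, Notch1 at 350 ± 82.4 and 276 ± 22.6, Notch3 at 75.6 ± 14.0 and 50.8 ± 11.5 and Dtx1 at 501 ± 16.0 and 458 ± 131. The lists of NOTCH targets (adjusted p = 0.354) and MYC targets (adjusted p = 0.626) did not pass. The ribosome biogenesis median was -0.05 without the TALL2 control and -0.14 without the TALL3 control. For RNA polymerase III it was -0.09 without the TALL2 control and -0.08 without TALL3 at 0 g/kg. Serine synthesis had 0.12 without the TALL3 control, 0.04 and 0.18 without TALL2 and TALL3 at 0 g/kg and 0.03 without its ATF4 targets. Mitosis had -0.16 without the TALL3 control and -0.46 without TALL3 at 0 g/kg.

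Genes of stress and of other cell types moved with the diet as well. Heat-shock and immediate-early genes rose (16 genes, median 0.99, adjusted p = 5.2e-08; adjusted p = 0.390 with an estimated correlation; 6 passed when adjusted over the list alone), with Fos at 17.3 and 6.61 FPKM in the controls and 58.8 and 61.3 FPKM without valine. The unfolded protein response rose (median 0.34, adjusted p = 1.6e-05), as did interferon-response genes (median 0.53, adjusted p = 1.8e-05) and genes of mature T-cell activation (median 0.62, adjusted p = 0.00151), each with an adjusted p of 0.613 with an estimated correlation. Without the TALL3 library at 0 g/kg these 3 lists had medians of 0.04, 0.02 and 0.15 and adjusted p values of 0.0728, 0.340 and 0.695. All 13 neutrophil markers were higher in both 0 g/kg libraries than in both controls, where chance gives 2.17 and the share over all genes 2.49, and all 13 passed when adjusted over the list alone (median 3.70, adjusted p = 1.9e-21; adjusted p = 0.390 with an estimated correlation). Adjusted over the list alone, 3 macrophage markers, 2 serine synthesis genes (Psat1 and Mthfd2), 2 mitochondrial ribosomal protein genes (Mrpl27 lower, Mrps6 higher), Sars and Uqcrfs1 passed too. The neutrophil markers S100a8 and S100a9 were at 108 and 194 FPKM in TALL2 and at 63.7 and 107 FPKM in TALL3 without valine, against at most 1.94 FPKM in the controls, and Retnlg was at 0.0496 ± 0.0702 and 15.2 ± 3.03 FPKM. Tested genes had to reach a mean of 1 FPKM over all 8 libraries, which Retnlg did only through the 0 g/kg libraries. The count of 13 neutrophil markers is therefore partly fixed by this filter. Macrophage markers rose (8 genes, median 0.39, adjusted p = 8.3e-04; adjusted p = 0.613 with an estimated correlation), led by Lyz2 at 0.804 ± 0.939 and 23.8 ± 4.13 FPKM, but not without the TALL2 control (adjusted p = 0.102). Erythroid markers fell (11 genes, median -1.97, adjusted p = 2.5e-09; adjusted p = 0.390 with an estimated correlation; 7 passed when adjusted over the list alone). The beta-globin gene Hbb-bs (chromosome 7, 103826534 to 103828096, minus strand) was at 58.9 and 156 FPKM in the controls and was listed at 0 in TALL2 and at 1.43 FPKM in TALL3 without valine. Its near-identical neighbour Hbb-bt shares reads with it, so the division between them is uncertain. Heat-shock genes had a median of 0.64 without the TALL3 control and 0.56 without TALL3 at 0 g/kg. Macrophage markers had 0.12 and 0.80 without the TALL2 and TALL3 controls and 0.68 and 0.11 without TALL2 and TALL3 at 0 g/kg. Interferon-response genes had 0.23 and 0.81 without the TALL2 and TALL3 controls and 1.02 without TALL2 at 0 g/kg, and T-cell activation had 1.27 without that library. With pseudocounts of 0.1 and 5 and with voom the neutrophil median was 5.89, 1.92 and 7.0, and the erythroid median -4.57, -1.16 and -6.0. The macrophage median was 0.18 with a pseudocount of 5 and 0.61 with voom.

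**Figure D2:**
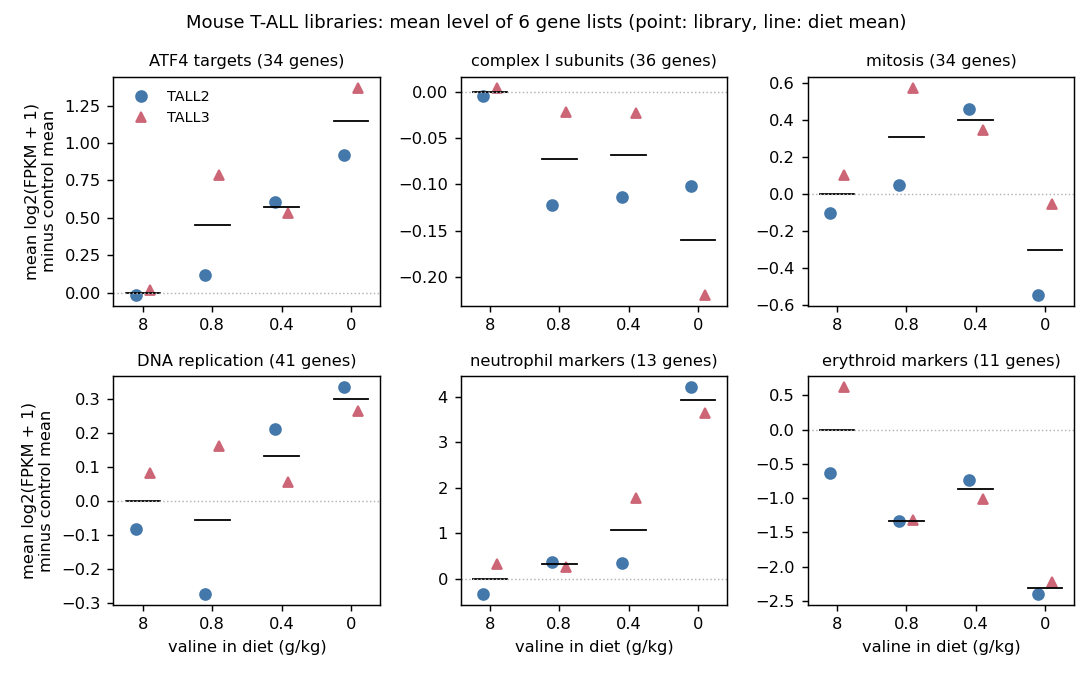
Mean log2(FPKM + 1) of 6 gene lists in each of the 8 mouse libraries, less the mean of the 2 control libraries, by valine in the diet (g/kg). Circles are TALL2, triangles TALL3 and lines diet means. The 34 ATF4 targets and 13 neutrophil markers were highest at 0 g/kg and the 36 complex I genes lowest, while mitosis genes were above the control mean at 0.4 g/kg and below it at 0 g/kg.

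At 0.4 g/kg against 8 g/kg, mitosis genes and ATF4 targets were higher and cytosolic ribosomal protein genes were lower. Mitosis genes rose by a median of 0.42 (34 genes, adjusted p = 3.1e-13; adjusted p = 0.740 with an estimated correlation), 32 of them higher in both libraries than in both controls where chance gives 5.67 and the share over all genes 5.75, with the topoisomerase Top2a at 205 ± 20.4 and 307 ± 27.6 FPKM. ATF4 targets rose by a median of 0.45 (adjusted p = 6.2e-10; adjusted p = 0.740 with an estimated correlation). In both libraries 24 of them were higher, where the share over all genes gives 5.75, and Jdp2 and Wars, named after their values were seen, were lower. Asns was at 47.3 and 17.1 FPKM, Mthfd2 at 77.9 ± 11.9 FPKM, and Bcat1 at 8.57 ± 1.98 FPKM. Cytosolic ribosomal proteins fell by a median of 0.17 (70 genes, adjusted p = 1.9e-04; adjusted p = 0.740 with an estimated correlation), 40 lower in both libraries where chance gives 11.7 and the share over all genes 22.3, including Rpl5 (31.8 ± 3.09 and 15.3 ± 3.20 FPKM). Without TALL2 at 0.4 g/kg the ribosomal protein median was -0.11 (adjusted p = 0.0234).

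Limma called 0 genes at 0.4 g/kg, with 1059 at an unadjusted p under 0.05, and voom called 0, with 1130. Of the 15 lists that passed, the unfolded protein response (median 0.20, adjusted p = 3.6e-06), cytosolic synthetases (median 0.23, adjusted p = 3.1e-05) and neutrophil markers (median 0.86, adjusted p = 3.7e-06) also rose and kept their call without each library, with an adjusted p of 0.740 for each with an estimated correlation. Without TALL2 at 0.4 g/kg their medians were 0.34, 0.11 and 1.47, and without TALL3 those of the unfolded protein response and neutrophil markers were 0.12 and 0.32. S100a9 was at 3.50 FPKM in TALL2 and 23.8 FPKM in TALL3. The other 9 lists lost their call without at least 1 library: higher interferon response (median 0.32), DNA replication (0.16), mature T-cell activation (0.44), heat shock (0.24) and serine, one-carbon and nucleotide synthesis (0.05), and lower cholesterol synthesis (-0.29), RNA polymerase III (-0.13), tRNA processing (-0.10) and erythroid markers (-1.11). Their largest adjusted p with an estimated correlation was 0.798. Without the TALL2 control the adjusted p was 0.265 for cholesterol synthesis (median -0.13), 0.125 for RNA polymerase III, 0.0716 for tRNA processing, 0.125 for serine synthesis (whose median turned to -0.03), 0.0602 for DNA replication and 0.0577 for interferon response. Without the TALL3 control it was 0.656 for erythroid markers (median -0.43), 0.490 for heat shock (0.07), 0.0507 for T-cell activation and 0.0681 for tRNA processing. Without the TALL3 library at 0.4 g/kg it was 0.477 for heat shock, whose median turned to -0.11, 0.0841 for T-cell activation (0.01), 0.0678 for erythroid markers, 0.0760 for RNA polymerase III and 0.0917 for tRNA processing. Without the TALL2 library at 0.4 g/kg it was 0.126 for DNA replication, 0.476 for serine synthesis and 0.0657 for RNA polymerase III. The tRNA processing list also ended without either 0 g/kg library (0.0514 and 0.0523). Voom, a filter at a mean of 5 FPKM, a pseudocount of 0.1 and only the 2 diets compared ended the erythroid call (0.0840, 0.0734, 0.125 and 0.0717). Median-of-ratios and quantile scaling ended those of tRNA processing (0.0780 and 0.0970) and RNA polymerase III (0.0636 and 0.0704). Quantile scaling ended that of serine synthesis (0.0613), as did leaving out its ATF4 targets (0.226), and only the 2 diets compared that of tRNA processing (0.0548). Adjusted over the list alone, 4 erythroid markers and Hsph1 of the heat-shock list passed. Complex I genes had a median of -0.06 (adjusted p = 0.511). Of the 36, 14 were lower and Ndufc1, Ndufs1 and Ndufs6 higher in both libraries, where chance gives 6.00 per direction and the share over all genes 11.5 lower and 6.09 higher. Further medians moved by over 1.5 times. Without the TALL2 control, DNA replication had 0.09, interferon response 0.15 and heat shock 0.44. Without the TALL3 control, cholesterol synthesis had -0.45, serine synthesis 0.11, DNA replication 0.23 and interferon response 0.63. Without TALL2 at 0.4 g/kg, serine synthesis had 0.00, DNA replication 0.07, interferon response 0.50 and heat shock 0.56. Without TALL3 at 0.4 g/kg, serine synthesis had 0.14 and interferon response 0.12. Erythroid markers had -0.73 without either 0 g/kg library and with only the 2 diets compared, -0.36 with no filter and -0.45 with a pseudocount of 5. Neutrophil markers had 2.30 and 0.27 with pseudocounts of 0.1 and 5, 1.88 with a filter at a mean of 5 FPKM and with only the 2 diets compared, and 2.79 with voom. A pseudocount of 5 gave 0.19 for interferon response, 0.12 for heat shock and 0.26 for T-cell activation, and that filter 0.21 for interferon response and 0.14 for heat shock. Median-of-ratios scaling gave -0.08 for RNA polymerase III, -0.04 for tRNA processing and 0.11 for serine synthesis, and quantile scaling -0.03 for tRNA processing and 0.09 for serine synthesis. Without shared ATF4 targets synthetases had 0.06 and serine synthesis 0.03.

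At 0.8 g/kg, the mildest restriction, erythroid markers were lower and genes of the unfolded protein response slightly higher than at 8 g/kg. Erythroid markers fell by a median of 1.25 (11 genes, adjusted p = 1.1e-07; adjusted p = 0.747 with an estimated correlation; 5 passed when adjusted over the list alone), with Hba-a1 at 20.8 ± 13.2 FPKM in the control and 3.13 ± 0.468 FPKM at 0.8 g/kg. The unfolded protein response rose by a median of 0.14 (25 genes, adjusted p = 4.5e-05; adjusted p = 0.747 with an estimated correlation), with Pdia4 at 51.9 ± 1.07 and 73.6 ± 6.36 FPKM and Hyou1 at 41.0 ± 1.90 and 53.3 ± 0.224. These 2 lists kept their call without each library, with a median of -2.23 for erythroid markers without the TALL2 control and of 0.07 for the unfolded protein response without TALL3 at 0.8 g/kg. ATF4 targets (median 0.26, adjusted p = 1.7e-08) and mitosis genes (median 0.31, adjusted p = 4.4e-13) rose as well, both at an adjusted p of 0.747 with an estimated correlation, but both calls rested on the TALL3 library at 0.8 g/kg. Asns was at 5.58 FPKM in TALL2 and 47.5 FPKM in TALL3, and without that TALL3 library the adjusted p was 0.131 for ATF4 targets (median 0.01) and 0.0525 for mitosis (0.03). Without TALL2 at 0.8 g/kg the medians were 0.50 for ATF4 targets and 0.55 for mitosis, and without the TALL2 control 0.19 for mitosis. Erythroid markers had -1.88 with a pseudocount of 0.1 and -2.03 with voom.

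Limma called 0 genes at 0.8 g/kg, with 433 at an unadjusted p under 0.05 where chance gives 497, and voom called 0, with 439. Of the 12 lists that passed, the other 8 were slightly higher cytosolic synthetases (median 0.12), interferon response (0.19), amino acid transporters (0.13) and neutrophil markers (0.17), and lower cholesterol synthesis (-0.27), ribosome biogenesis (-0.11), RNA polymerase III (-0.11) and tRNA processing (-0.11), with adjusted p values from 0.00116 to 0.0404 and from 0.747 to 0.960 with an estimated correlation. Each lost its call without 1 of the compared libraries: synthetases without TALL3 at 0.8 g/kg (median turned to -0.03, adjusted p = 0.693), interferon response without TALL3 at 0.8 g/kg (turned to -0.01, 0.166) or the TALL2 control (turned to -0.02, 0.413), and tRNA processing without TALL2 at 0.8 g/kg (0.643) or the TALL3 control (0.0623). Without TALL2 at 0.8 g/kg or the TALL2 control, the adjusted p was 0.117 and 0.473 for cholesterol synthesis, 0.117 and 0.265 for ribosome biogenesis, 0.168 and 0.0848 for RNA polymerase III, 0.442 and 0.501 for neutrophil markers (medians 0.09 and, turned, -0.08) and 0.168 and 0.0542 for transporters. Transporters also ended without TALL3 at 0.8 g/kg (0.0605), without the TALL3 control (0.139), with voom (0.0526), with a filter at a mean of 5 FPKM (0.0785), with quantile scaling (0.0588) and without the shared ATF4 targets (0.390). Neutrophil markers also ended without either 0 g/kg library (0.0547 and 0.0722), with a pseudocount of 5 (0.126), with that filter (0.0605), and with median-of-ratios (0.214) or quantile scaling (0.134). Complex I genes had a median of -0.08 (adjusted p = 0.13), which passed without the TALL3 library at 0.8 g/kg (median -0.14, adjusted p = 0.0251). Medians without the TALL2 control were -0.04 for ribosome biogenesis and -0.11 for cholesterol synthesis. Without the TALL3 control they were -0.45 for cholesterol synthesis, 0.48 for interferon response and 0.38 for neutrophil markers. Without TALL2 at 0.8 g/kg they were 0.20 for synthetases, -0.07 for tRNA processing, 0.04 for transporters and 0.39 for interferon response. Transporters had 0.03 without TALL3 at 0.8 g/kg and 0.02 without the shared ATF4 targets. Neutrophil markers had 0.30 without TALL2 at 0 g/kg, 1.11 and 0.04 with pseudocounts of 0.1 and 5, 0.69 with a filter at a mean of 5 FPKM and 1.54 with voom, which gave 0.40 for interferon response. Median-of-ratios scaling gave -0.06 for ribosome biogenesis and -0.07 for RNA polymerase III and for tRNA processing, and quantile scaling -0.06 for both of the latter.

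A slope over the ranked diets asked which genes moved as valine fell. ATF4 targets rose by a median of 0.26 per rank (adjusted p = 2.4e-20; adjusted p = 0.360 with an estimated correlation), with 23 of 34 genes passing when adjusted over the list alone. Sars, the seryl-tRNA synthetase, was at 48.4 and 47.6 FPKM at 8 g/kg, 57.6 and 75.6 at 0.8 g/kg, 74.7 and 69.8 at 0.4 g/kg and 81.6 and 85.4 at 0 g/kg (adjusted p = 0.182). Mrpl27 of the mitochondrial ribosome went the other way, from 17.1 and 16.5 FPKM through 13.5 and 13.2, then 12.4 and 11.9, to 11.1 and 9.88 (slope -0.20, SE 0.0291, adjusted p = 0.182). Myc was at 267 and 222 FPKM, 185 and 202, 178 and 156, and 161 and 112 (slope -0.28, SE 0.0528, adjusted p = 0.183). Complex I genes fell by a median of 0.05 per rank (adjusted p = 4.0e-05; adjusted p = 0.551 with an estimated correlation), with Ndufb11 at 45.4 and 45.3 FPKM at 8 g/kg and at 38.9 and 36.0 FPKM at 0 g/kg, and the list did not pass without the TALL3 library at 0 g/kg (adjusted p = 0.0704). The fall was not stepwise: the medians against the control were -0.08, -0.06 and -0.18 at 0.8, 0.4 and 0 g/kg. Without TALL3 at 0 g/kg the complex I slope was -0.04.

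Limma called 0 genes for the slope, with 1220 at an unadjusted p under 0.05, and voom called 0, with 1175. Without the TALL3 library at 0.8 g/kg, Asns and Sars passed (adjusted p = 0.0368 each), and without the TALL2 library at 0.4 g/kg S100a9 did (adjusted p = 0.0373). Of the 20 lists that passed, 10 kept their call without each of the 8 libraries: ATF4 targets, transporters, synthetases, DNA replication, erythroid markers, heat shock, interferon response, neutrophil markers, RNA polymerase III and the unfolded protein response. Without the shared ATF4 targets the transporter list did not pass (median 0.00, adjusted p = 0.880), nor did serine synthesis (0.0605), while synthetases did (0.00923). Adjusted over the list alone, 12 neutrophil markers and 10 synthetases rose, Aimp1 of the synthetase list fell, and 6 erythroid markers fell. Without the TALL3 library at 0 g/kg 11 lists passed, and the adjusted p was 0.220 for complexes II to IV, 0.986 for the TCA cycle, 0.311 for mitochondrial ribosomal proteins, 0.0820 for ribosome biogenesis and for T-cell activation, 0.0767 for tRNA processing and 0.279 for macrophage markers, whose median turned to -0.02. Without the TALL2 library at 0 g/kg it was 0.0620 for serine synthesis and 0.0701 for macrophage markers. Without the TALL2 control it was 0.159 for ribosome biogenesis, 0.0531 for tRNA processing and 0.106 for macrophage markers. The TCA cycle ended without the TALL3 control (0.0736) or TALL3 at 0.8 g/kg (0.0791), and mitosis without TALL2 (0.0573) or TALL3 (0.210) at 0.8 g/kg or TALL3 at 0 g/kg (0.311). The TCA cycle (0.0752, 0.0596, 0.0665, 0.0567 and 0.0665) and mitosis (0.0779, 0.0513, 0.115, 0.0516 and 0.0724) also ended with a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile scaling, no variance trend and voom. Mitosis ended with a pseudocount of 5 as well (0.0520). With an estimated correlation the adjusted p of the 20 lists lay between 0.360 and 0.884. The mitosis slope (median -0.07, adjusted p = 0.0444) turned to a median of 0.05 (adjusted p = 0.0497) without the TALL2 library at 0 g/kg. Slopes moved by over 1.5 times without the TALL2 control for ribosome biogenesis (-0.01), synthetases (0.04), mitosis (-0.14), interferon response (0.09) and the unfolded protein response (0.07). Without the TALL3 control this held for mitochondrial ribosomal proteins (-0.01), serine synthesis (0.05) and macrophage markers (0.25), and without TALL2 at 0.8 g/kg for ribosome biogenesis (-0.03) and serine synthesis (0.02). Transporters had 0.03 without TALL3 at 0.8 or at 0.4 g/kg and with a pseudocount of 5. Without TALL2 at 0 g/kg, ribosome biogenesis had -0.04, interferon response 0.26 and T-cell activation 0.35. Without TALL3 at 0 g/kg, the TCA cycle had -0.01, interferon response 0.05, the unfolded protein response 0.04 and T-cell activation 0.11. With pseudocounts of 0.1 and 5 and with voom neutrophil markers had 1.92, 0.60 and 3.02 and erythroid markers -1.36, -0.30 and -1.46, and macrophage markers had 0.05 with a pseudocount of 5. Mitosis had -0.12 without both 0.4 g/kg libraries. Without the shared ATF4 targets synthetases had 0.04 and serine synthesis 0.02.

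The 3 restricted diets were also compared with one another. Limma's F test called 0 genes, with 376 at an unadjusted p under 0.05 where chance gives 497, and voom called 0, with 365. The list tests that follow were chosen after those against the control had been seen. The share over all genes was not computed for these pairs of diets. Mitosis genes were lower at 0 g/kg than at 0.4 g/kg (median -0.65, adjusted p = 1.5e-36; 33 of 34 lower in both libraries, chance 5.67) and than at 0.8 g/kg (median -0.56, adjusted p = 2.2e-27; 24 lower). The adjusted p with an estimated correlation was 0.484 and 0.583. Complex I genes were lower at 0 g/kg than at 0.4 g/kg (median -0.09, adjusted p = 2.9e-06) and than at 0.8 g/kg (median -0.07, adjusted p = 5.9e-05), with 0.549 and 0.623 with an estimated correlation. ATF4 targets were higher at 0 g/kg than at 0.4 g/kg (median 0.37, adjusted p = 5.5e-07) and than at 0.8 g/kg (median 0.46, adjusted p = 7.5e-13), with 0.549 and 0.583 with an estimated correlation, and so were neutrophil markers (medians 2.83 and 3.49, adjusted p = 5.3e-21 and 3.4e-27, with 0.484 and 0.583 with an estimated correlation). From 0.8 to 0.4 g/kg complex I genes did not pass (median 0.01, adjusted p = 0.643), ribosomal proteins were lower (median -0.10, adjusted p = 1.1e-09), and mitosis genes (median 0.08, adjusted p = 0.00310) and, against their falling slope, erythroid markers (median 0.52, adjusted p = 2.7e-04) were higher. The adjusted p of these 4 lists with an estimated correlation was 0.893 to 0.899. Of the 34 mitosis genes, 0 were higher in both 0.4 g/kg libraries than in both 0.8 g/kg libraries. From 0.4 to 0 g/kg ribosomal proteins turned higher (median 0.13, camera adjusted p = 9.1e-07, and 0.484 with an estimated correlation).

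In data simulated with 2 libraries per diet for 0 against 8 g/kg, limma called 92 genes, 3 of them false, where no measured gene passed. It recovered 11.9% of simulated genes changed by 1.5-fold, 41.8% of those changed by 2-fold and 80.3% of those changed by 4-fold. The simulated noise was independent between libraries, whereas measured deviations recurred between diets, so recovery in the measured libraries may differ. Large changes are not excluded by the lack of calls. Asns, at 2.02 and 2.90 FPKM in the controls and 69.2 and 84.6 FPKM without valine, did not pass. The TALL3 library at 0.4 g/kg stood apart from the other TALL3 libraries: on a scale from TALL2 (0) to TALL3 (1) it lay at 0.395, and they at 0.795 to 0.978. Without both 0.4 g/kg libraries, a setting chosen after seeing the data, 22 lists passed for 0 against 8 g/kg, 12 for 0.8 against 8 g/kg and 21 for the slope.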

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

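The tests with limma-voom on recovered reads and those without both 0.4 g/kg libraries were chosen after seeing the data, and the other settings below were planned. In KOPTK1 the 3547 called genes became 5374 with no filter and 1139 with a filter at a mean of 5 FPKM, which change the number of genes tested, and 2207 (without gSI replicate 2) to 3555 (without DMSO replicate 2) with a library left out. Voom called 3680 genes, 3410 of them shared. It used the authors' divisors as library sizes, so it is no check on the scaling. The median of complex I genes there lay between -0.10 and -0.01 with a library left out.

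With an estimated correlation the number of lists called was 0 in KOPTK1, 0 at 0 g/kg, 0 at 0.4 g/kg, 0 at 0.8 g/kg and 0 for the slope, against 13, 21, 15, 12 and 20 with camera's preset; limma's gene counts at an unadjusted p under 0.05 were 3891, 1025, 1059, 433 and 1220, and voom's list counts were 12, 21, 14, 11 and 18. Fry, which tests each list alone, called 2 lists at 0 g/kg, 0 at 0.4 g/kg, 0 at 0.8 g/kg and 4 for the slope. In KOPTK1 its number of called lists was within 1.5 times that of camera. The complex I list at 0 g/kg has its median of -0.18 under both tests, with an adjusted p of 0.613 with an estimated correlation and 0.285 with fry. At 0.8 g/kg its median ran from -0.14 (without TALL3 at 0.8 g/kg, adjusted p = 0.0251) to -0.031 (without TALL2 at 0.8 g/kg). The cause was not tested.

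For the slope the genes called with a library left out ran from 0 to 2 (without TALL3 at 0.8 g/kg), with 1 without TALL2 at 0.4 g/kg, and the lists from 11 (without TALL3 at 0 g/kg) to 23 (without TALL2 at 0 g/kg). The mitosis slope ran from -0.14 (without the TALL2 control) to 0.049 (without TALL2 at 0 g/kg), a reversal whose cause was not tested. Where a group kept 1 library, that library is assumed to vary like the others. Without both 0.4 g/kg libraries 22, 12 and 21 lists passed for 0 and 0.8 against 8 g/kg and the slope.

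The labels do not say that libraries with the same replicate or TALL number share a source. With the number as a block 3705 KOPTK1 genes were called and 11, 21, 13, 13 and 20 lists passed, and limma called 0 genes in each diet comparison, with 1230, 1266 and 542 at an unadjusted p under 0.05 for 0, 0.4 and 0.8 against 8 g/kg, where voom without the block also called 0. In camera the block ended the calls of RNA polymerase III (adjusted p = 0.0513) and tRNA processing (0.0582) at 0.4 g/kg. In KOPTK1 it ended those of mitochondrial ribosomal proteins (0.170) and heat shock (0.0905). The correlation of deviations across genes was 0.258 in KOPTK1 and from -0.17 to 0.74 between diets, with 0.06 and -0.17 for 0.4 against 8 and 0.8 g/kg and 0.36 or more for the other diet pairs. The shallowest library held 14222895 reads, and the effect of depth on genes with low FPKM was not tested.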

Other observations

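Except for the tests on ATF4 targets with the neutrophil level, on gene length, on GC content and on a single mixing share, the tests below were chosen only after the result was seen. Lists of fewer than 5 tested genes were not tested. At 0 against 8 g/kg the 3 B-cell markers Cd22, Cd74 and Blk had a median log2 fold change of 2.21, the 3 plasma-cell markers 0.48, the 3 natural killer markers 0.62, the 2 dendritic-cell markers 0.27, the 3 markers of stroma and endothelium 0.11, the 1 platelet marker 0.69 and the 2 progenitor markers 0.68. Cd74 was at 73.0 FPKM in TALL3 at 0 g/kg against 13.7 FPKM in the TALL3 control.

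In the 0 g/kg libraries neutrophil markers were higher and erythroid markers lower, although the cells had been sorted for GFP. All 13 tested neutrophil markers were higher in both 0 g/kg libraries than in both controls, but this restates the pattern, so whether neutrophils were among the sorted cells stays open. A lower share of leukaemic cells alone would raise all other cell types alike, and the erythroid median of -1.97 argues against that cause acting alone. The medians of the other cell-type lists were all positive. The filter on the mean over all libraries can favour markers that are high at 0 g/kg, so these signs may be partly fixed by it. A lower share together with a separate fall of erythroid markers therefore stays open. Neutrophil RNA could also have raised the ATF4 list. With the neutrophil level as a covariate the list's median slope was 0.26 (0.26 before), with a camera adjusted p of 8.5e-11 at the preset correlation. An estimated correlation was not run for this fit. The neutrophil level and the diet rank correlated at 0.873 over the libraries. The fit can therefore separate them only weakly. Asns, a gene fixed beforehand, was at 47.5 FPKM in TALL3 at 0.8 g/kg and 47.3 FPKM in TALL2 at 0.4 g/kg. S100a9 was there at 2.17 and 3.50 FPKM. In TALL2 at 0.8 g/kg and TALL3 at 0.4 g/kg, Asns was at 5.58 and 17.1 FPKM and S100a9 at 5.59 and 23.8 FPKM. Asns was thus high in libraries with little of this neutrophil marker. For the list at 0 g/kg neutrophil RNA stays open as a source. A change of the blood cells themselves by diet stays open and was not tested.

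The complex I list was lower at 0 g/kg. Its genes are short, with a median of 1008.5 bp against 3139 bp over all tested genes, so a length trend between libraries could shift them. With that trend removed the median went from -0.18 to -0.11, which kept 61.2% of its size (adjusted p = 4.8e-04), so length may account for part of the shift and not for all of it. With a GC trend removed the median was -0.18, 98.3% of its size. The diet itself stays open as a hypothesis, with the adjusted p of 0.613 under an estimated correlation.

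The 0.4 g/kg libraries lay closer together than those of other diets in genes that differ between TALL2 and TALL3. Without these 2 libraries limma called 294 genes between TALL3 and TALL2, and over all 4 diets it called 1, 1700048O20Rik. On a scale from TALL2 (0) to TALL3 (1) the library labelled TALL2 lay at 0.222, which argues against exchanged labels. The one labelled TALL3 lay at 0.395, above the TALL2 libraries of the other diets (0.026 to 0.085). The TALL2 library at 0.4 g/kg lay above them too, with quartiles over genes of 0.021 and 0.425. TALL2 cells alone can therefore not be excluded. A mixture could also place the library labelled TALL3 there. The shares of TALL3 read from genes higher in TALL3 and from genes higher in TALL2 differed by 0.50. The limit of 0.2 set for this beforehand was wrong, since a library of another diet differed by 0.378, and a mixture cannot be told apart from another source.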
